A study of Mus musculus with 73 samples.

How the data were processed

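The material was 73 hand-picked single cells of mouse cochlea at postnatal day 14, all labelled as Casz1-null inner hair cells. Per the labels' protocols, the tissue was digested with papain, protease and dispase. Full-length cDNA was made with the Smart-Seq HT kit, and libraries were made by tagmentation. The submitters' processing notes name HISAT2 2.2.1, StringTie 2.2.1 and featureCounts 2.0.1 and the genome build mm10. They do not give the role, order or settings of the tools, and the annotation release is not given in the sources used here. The authors deposited whole-number counts per gene and cell in 1 table of 55292 rows. The kit carries no molecular identifiers, so counts include PCR copies. Because the counting is not stated to use strand, genes that overlap or have an antisense partner, and near-identical copies such as pseudogenes, are uncertain.

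All 73 columns matched a sample title. The last row of the table is the reporter element WPRE, which is 0.0161% of counts and was kept out of library totals, leaving 55291 gene rows, of which 27502 had a count. No 2 libraries were identical: the lowest chi-square per gene between 2 libraries was 484 over 2628 pairs. Total counts ranged from 11027945 to 37183702, so 1 count is 0.0907 CPM in the shallowest library and 0.0269 CPM in the deepest.

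Counts were divided by the library total to give CPM, and correlations and scores used log2(CPM + 1). Detection meant 10 CPM or more, and shares carry exact Clopper-Pearson 95% intervals. For 0 of 73 cells, a rule of 3 counts allows a share of up to 4.11%, and the exact upper limit is 4.93%. The design has 1 group, and the labels name no animal, so no test between groups and no p-value was made, and a count model was not used. Rank correlations over cells are Spearman values for the 8619 genes with a mean of 10 CPM or more, Slc26a5 included. The median of a gene list was placed among 10000 random lists of the same size, drawn from 50 bins of mean expression. This percentile describes these libraries and is not a p-value. Random lists were not matched on how variable the genes are.

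Clusters used 2000 variable genes without the inner hair cell, outer hair cell, sex-linked and mitochondrial genes, 15 principal components, 10 neighbours and Leiden resolution 1. A cluster would be named only from at least 3 markers of 1 class. No doublet caller was run, because cells were picked by hand. Variable genes were ranked by the excess of the log10 squared coefficient of variation over a lowess trend (span 0.3) on log10 mean CPM. Gene positions and the lengths of the 26 genes of both lists come from the GENCODE vM21 annotation of the same build, whose symbols match 53292 gene rows and 98.6% of counts.

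The 21 gene lists (211 genes), the thresholds, most alternatives of the closing section and the rule for named genes were fixed before the data were examined. The text names members of these lists, the 20 genes with the highest mean, the 15 highest and 15 lowest genes by correlation with Slc26a5, and the 20 most variable genes, skipping genes without an official name. A few genes that this rule names are not reported here. Groups of ribosomal protein and mitochondrial genes, lymphocyte markers and correlations within clusters were added after the values were seen.

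The correlation step was tested on simulated counts for 8619 genes over 73 cells. It recovered 29.4%, 64.7% and 100% of genes rising by 0.5, 1 and 2 log2 units per SD of a hidden variable. For falling genes it recovered 35.3%, 85.3% and 100%. Slc26a5 was simulated to rise by 2 log2 units per SD of that variable. Simulated genes rising by 2 units had a median correlation of 0.97 with Slc26a5, above the highest in the data (0.84). Recovery may therefore be lower in the data. Of 8418 unchanged genes, 0 reached 0.5 in size. They were drawn independently of each other, so this gives no rate of false calls for real cells. The step for variable genes recovered 94 of 100 genes simulated with 10 times the squared coefficient of variation of the trend. All other genes were simulated on the trend, without the scatter of real genes, so recovery may be lower in the data. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, statsmodels 0.14.6, python-igraph 0.11.9 and matplotlib 3.10.9, with R 4.3.3 and scran 1.30.0 for an alternative scaling.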

Results

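Inner hair cells (IHCs) are the sensory cells of the cochlea that pass sound to the auditory nerve, and outer hair cells (OHCs) amplify it. The study deleted Casz1, a zinc-finger transcription factor, and asked what happens to inner hair cell fate. The data analysed here are 73 full-length single-cell transcriptomes of inner hair cells from mouse cochleae at postnatal day 14. Cre expressed from Atoh1, a gene of developing hair cells, removed Casz1 and switched on GFP. Flp expressed from Fgf8, an inner hair cell gene, switched on tdTomato, and cells with both colours were picked by hand. The cells form 1 group. The labels name no animal, so the 73 cells counted as 1 sample with no replicates, and the wild-type cells of the study were not analysed here. The values below therefore describe these libraries, with no p-values and no statement on what the deletion changed. Each library held 11027945 to 37183702 counts (median 17333640), and 6954 to 10688 genes had a count (median 8518). Levels are given in CPM, counts scaled by the library total. A gene was called detected at 10 CPM, which is 110 counts in the shallowest library and 372 in the deepest. Intervals are exact 95% Clopper-Pearson intervals over cells and cover counting error only.

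Casz1 reads were present in most of the cells labelled null. The gene lies on chromosome 4 from 148804429 to 148954889 on the plus strand of mm10. Its median level was 42.1 CPM (quartiles 10.0 and 75.4, range 0 to 283). It was detected in 55 of 73 cells (75.3%, interval 63.9 to 84.7), and 2 cells had no read. The share depended on the threshold, at 87.7% for 1 CPM and 42.5% for 50 CPM. The labels do not state which exons were removed, and reads from the remaining exons still count, so this gene does not check the deletion.

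The picked cells carried the transcripts shared by all hair cells. Of the 16 general hair cell genes, 11 were detected in all 73 cells, and a median of 15 were detected per cell (range 12 to 16). Myo7a and Myo6, motor proteins of the hair bundle and cell body, had medians of 381 and 1788 CPM. Pou4f3, a transcription factor needed for hair cell survival, had a median of 450 CPM. Tmc1, a subunit of the mechanotransduction channel, had a median of 447 CPM, and Cib2, its partner, 3751 CPM. Less regular members were Chrna9 in 51 cells, Barhl1 in 48 and Lhx3 in 31. Among the genes with the highest mean levels were Calm2 (15714 CPM), which encodes the calcium sensor calmodulin, Skp1a (14019 CPM), Malat1, Gpx2 and Calb2.

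Inner hair cell transcripts were detected unevenly, some in every cell and others in few. Slc17a8, the transporter that loads glutamate into synaptic vesicles, was detected in all 73 cells at a median of 1346 CPM (range 436 to 2992). Otof, the calcium sensor of vesicle release, was also in all 73 cells (median 2912 CPM), as were Gata3 (252 CPM) and Calb2 (8135 CPM). Tbx2, a transcription factor of inner hair cell fate, was detected in 61 cells (83.6%, interval 73.0 to 91.2). Dnajc5b was found in 72 cells and Slc7a14 in 63. Atp2a3, a calcium pump of the endoplasmic reticulum, ranged from 0 to 2248 CPM and was detected in 53 cells (72.6%, interval 60.9 to 82.4). Fgf8 was detected in 51 cells and Shtn1 in 50, while Rprm was in 17 and Brip1 in 9. A median of 9 of the 12 list members was detected per cell.

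Outer hair cell transcripts were present in the same cells. Slc26a5, which encodes prestin, the motor protein of outer hair cells, was detected in 51 of 73 cells (69.9%, interval 57.999 to 80.056). It lies on chromosome 5 from 21810655 to 21865604 on the minus strand. Its level ran from 0 in 4 cells through 19 cells at 10 to 100 CPM to 32 cells at 100 CPM or more, with a maximum of 1229 CPM. Ocm, a calcium-binding protein abundant in outer hair cells, was detected in 68 cells at a median of 2112 CPM and a maximum of 17081 CPM. Sri, Mlf1 and Car7 were detected in 71, 73 and 73 cells. Kcnn2, the calcium-activated potassium channel of efferent synapses, was detected in 63 cells.

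Several regulators of outer hair cells were rare. Ikzf2, a transcription factor of outer hair cell maturation, was detected in 6 cells (8.22%, interval 3.076 to 17.036). Bcl11b was detected in 1 cell. Insm1, which is expressed in embryonic outer hair cells, was detected in 0 of 73 cells, which allows a share of up to 4.11% by a rule of 3 counts and 4.93% by the exact interval. Lbh was detected in 20 cells, and Chrna10, a subunit of the efferent acetylcholine receptor, in 31. A median of 8 of the 14 outer hair cell genes was detected per cell. In clusters 1 to 4 described below, the median was 9, 8, 7 and 6. Cluster 4 thus had a median of 6 although Slc26a5 was detected in 0 of its 11 cells, with Car7 and Mlf1 in all 11. The count therefore does not depend on Slc26a5 alone.

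**Figure D1:**
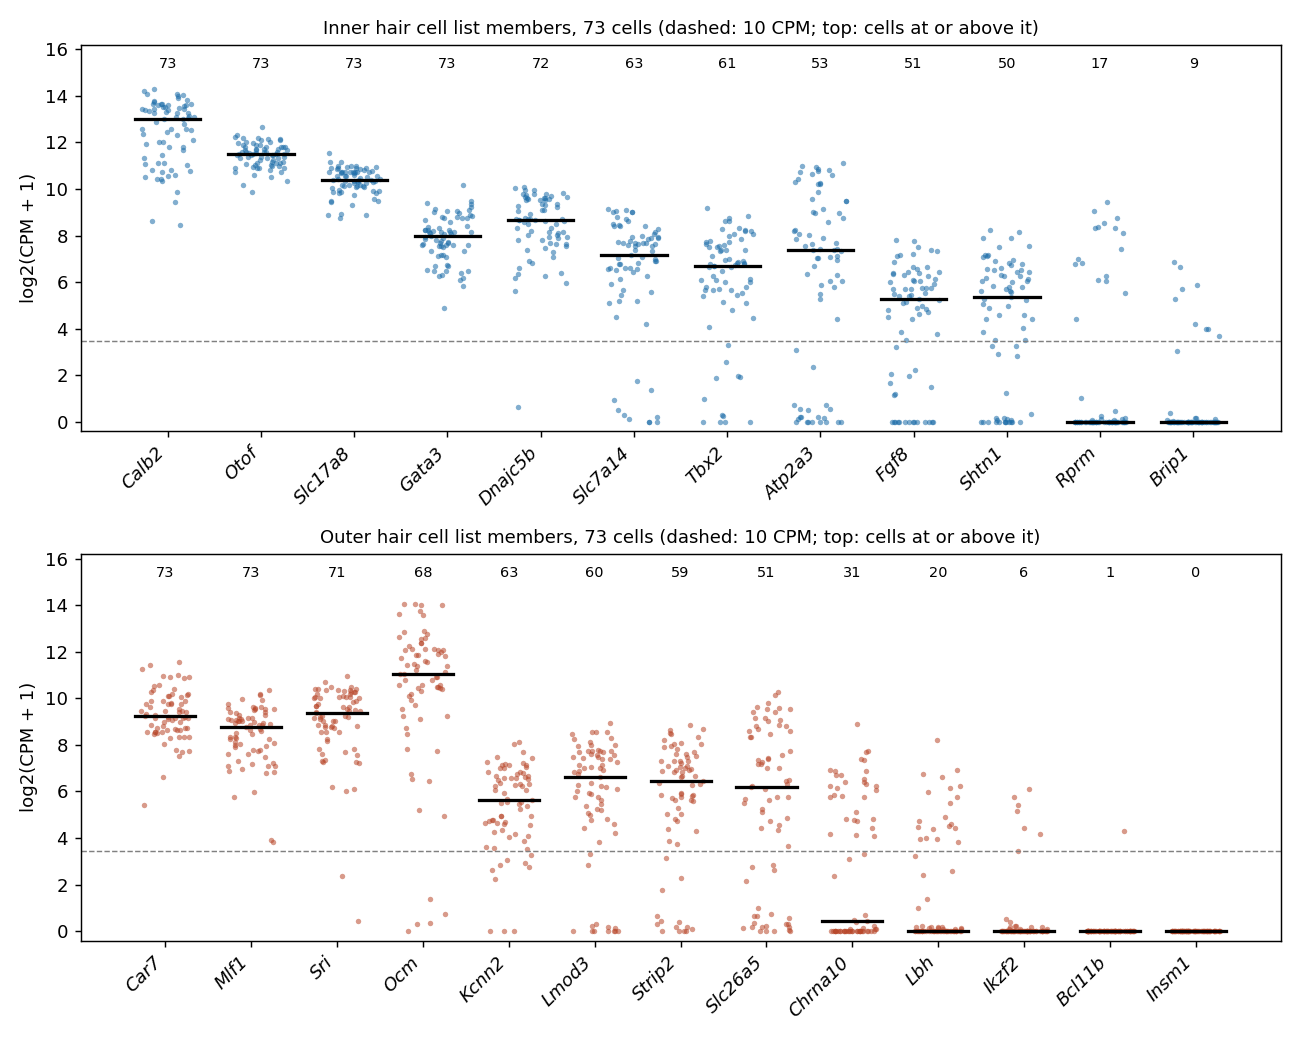
Each point is the level of a gene in 1 of the 73 cells, as log2(CPM + 1), for members of the inner hair cell list (top) and the outer hair cell list (bottom). Bars mark medians, the dashed line 10 CPM and the numbers the cells at or above it: Slc17a8 is in all 73 cells, Slc26a5 in 51 and Ikzf2 in 6.

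Slc26a5 and Slc17a8 were found in the same cells. Because Slc17a8 was in all 73 cells, the 51 cells with Slc26a5 all held both, and the other 22 cells held Slc17a8 alone. The share of cells with both is therefore the share with Slc26a5, 69.9%, which was 94.5% when a single count was enough and 56.2% at 50 CPM. Of Slc26a5 and Atp2a3, 31 cells had both, 20 had Slc26a5 alone, 22 had Atp2a3 alone and 0 had neither. All 6 cells with Ikzf2 and 19 of the 20 with Lbh also had Slc26a5, against 69.9% of all cells. For Ikzf2, 6 cells are too few to tell apart from that share. In clusters 1 to 4 described below, of 26, 23, 13 and 11 cells, Ikzf2 was detected in 1, 2, 3 and 0 cells. Lbh was detected in 14, 4, 1 and 1.

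A score per cell set the 2 lists against each other, as the mean log2(CPM + 1) of outer hair cell genes minus that of inner hair cell genes. Its median was -2.11 (SD over cells 1.53, range -4.89 to 1.54), and it was -1.39 with a pseudocount of 10 in place of 1 and -1.56 with counts divided by gene length. In 9 cells the outer hair cell mean was the higher, and in 10 with either alternative. The level of 0 has no biological meaning, because the lists hold different genes.

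Members of each list varied together over the cells, and the lists varied against each other. The median rank correlation between pairs of inner hair cell genes was 0.314 over 11 members, above all 10000 random lists matched on mean expression. For 10 outer hair cell genes it was 0.206, also above all random lists. Between the lists it was -0.179, below all random pairs of lists. Corrected for the mitochondrial share, the values were 0.180 within the inner hair cell list, 0.180 within the outer hair cell list and -0.120 between the lists. Corrected for immediate early genes as well, the value between the lists was -0.108. The uncorrected values were smaller inside the clusters of cells described below, which hold 11 to 26 cells each. The first principal component behind the clusters had a rank correlation of 0.80 in size with Slc26a5. Part of the variation thus lies between clusters, and the smaller values inside them do not test the lists. In clusters 1 to 4 the value between the lists was -0.11, -0.09, 0.02 and 0.02, leaving out genes that did not vary within a cluster. Within the inner hair cell list it was 0.17, 0.09, 0.09 and 0.05, and within the outer hair cell list 0.15, 0.17, 0.15 and 0.00.

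Slc26a5 tracked a broad set of transcripts over the cells. Of 8618 other genes with a mean of 10 CPM or more, 116 had a rank correlation of 0.5 or higher with Slc26a5 and 75 had one of -0.5 or lower. The genes ranked highest were Aqp11, an aquaporin (0.84), Calb1, a calcium buffer (0.77), Ocm (0.73) and Sri, a calcium-binding protein (0.72). Sirt2 (0.71), Pole (0.70), Prxl2a (0.70), App (0.68) and Atp8a2 (0.67) came next. Chrna9, the other subunit of the efferent acetylcholine receptor, reached 0.67, as did Mdh1, the potassium channel Kcnj13, Anxa5 and Tnc, and Rab27b reached 0.65. Fgf8, placed in the inner hair cell list, also rose with Slc26a5 (0.58), as did Rprm (0.50).

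Atp2a3 stood at the other end, with a rank correlation of -0.77. Rps6ka2 (-0.74), Tomm7 (-0.73), Ripor3 (-0.70) and Igfbp5 (-0.70) were also among the 15 lowest. Between Osbp2 (-0.69) and Dnajc5b (-0.63) stood Pdcd6, Chst2, Mlxipl, Map4k4, Shc2, Kcnab1 and Plekhg6. Slc7a14 stood at -0.58 and Tbx2 at -0.52, while Calb2 (-0.49), Gata3 (-0.41) and Slc17a8 (-0.32) did not reach -0.5. The value for Slc17a8 was -0.147 corrected for the mitochondrial share and -0.153 without the 22 cells in which a rare marker of another cell type reached 50 CPM, a subset that still holds commoner markers such as Sox10 and Cnp. Casz1 stood at -0.13, with -0.231 without those 22 cells, -0.064 corrected for genes detected and -0.068 for the mitochondrial share.

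Properties of the libraries moved with Slc26a5 too. Its rank correlation was -0.49 with the mitochondrial share of counts, which had a median of 6.06% (range 1.81 to 13.0). It was 0.27 with total counts and -0.30 with the number of genes. With the ribosomal protein share of counts it was 0.62, and with the mean log2 level of immediate early and stress genes -0.34. With ranks corrected for the mitochondrial share, 69 genes in place of 191 had a correlation of 0.5 or more in size. Within clusters 1 to 4 the correlation with Slc26a5 was 0.70, 0.46, 0.57 and 0.56 for Ocm, and 0.51, 0.45, 0.62 and 0.34 for Aqp11. For Atp2a3 it was -0.20, -0.23, -0.48 and -0.44, for Calb1 0.25, 0.25, 0.38 and -0.02, and for Fgf8 0.05, 0.22, 0.34 and 0.02. Some values differed in sign between clusters. Slc17a8 stood at 0.15, -0.25, 0.12 and 0.55, and Chrna9 at -0.20, 0.20, 0.29 and 0.51. Slc7a14 (-0.26, -0.32, -0.19 and 0.37) and Sri (0.12, 0.20, 0.42 and -0.10) did so only in cluster 4. In that cluster of 11 cells, Slc26a5 was detected in 0 cells (maximum 5.10 CPM). Every cluster 4 correlation with Slc26a5 given here therefore ranks levels below detection.

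**Figure D2:**
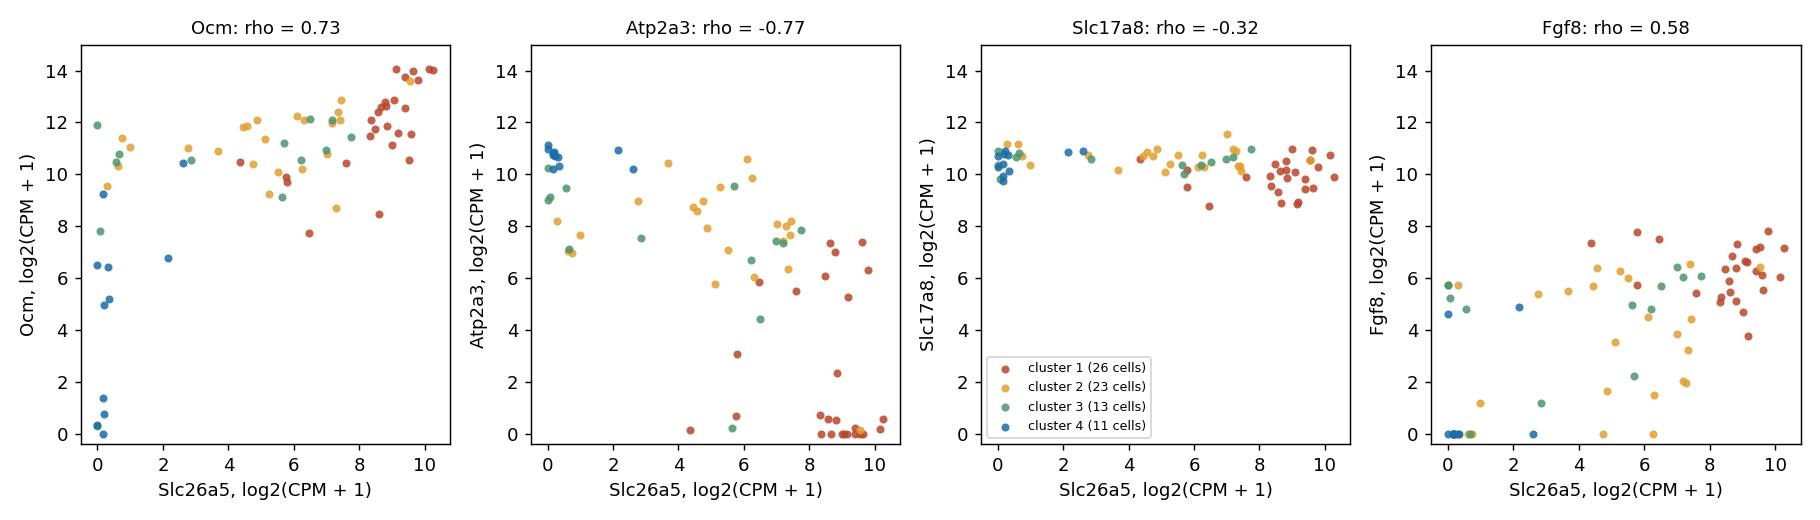
Each point is 1 of the 73 cells, with Slc26a5 on the horizontal axis and Ocm, Atp2a3, Slc17a8 or Fgf8 on the vertical axis, all as log2(CPM + 1), and colours mark the 4 clusters. Ocm rises along Slc26a5 (rank correlation 0.73), Atp2a3 falls (-0.77), and Slc17a8 stays between 436 and 2992 CPM in every cell.

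Gene groups of hair cell function differed in how they followed Slc26a5. Ribbon synapse genes, which serve vesicle release, had 14 of 18 members detected in at least 37 cells. Of 17 members compared, 13 had negative correlations with Slc26a5, with a median of -0.26 that lay below all matched random lists. Slc7a14 (-0.58), Otof (-0.37) and Slc17a8 (-0.32) among them are also in the inner hair cell list, so the lists are not independent. Erc2 (-0.51) and Rims2 (-0.48), scaffolds of the active zone, were among the lowest. Ion channel and pump genes had a median of 0.25 over 13 members, at percentile 99.95. Of these, Kcnn2 and Chrna10 are also in the outer hair cell list and Atp2a3 in the inner hair cell list. Chrna9, Kcnj13, the ATP-gated channel P2rx2 (0.63) and the plasma membrane calcium pump Atp2b2 (0.54) reached 0.5, and Atp2a3 alone reached -0.5, with Atp2b1 at -0.36 and Kcnma1 at -0.35. The 9 outer hair cell genes compared with Slc26a5 had a median of 0.26 (percentile 99.6). Only Ocm and Sri among them reached 0.5, and Car7 (-0.07) and Lmod3 (-0.10) were negative. Inner hair cell genes stood at -0.41, below all random lists, with 9 of 11 negative.

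Hair bundle genes went both ways. Of 27 members, 21 were detected in at least 37 cells, and of 25 compared with Slc26a5, 13 had positive and 12 negative correlations (median 0.03, percentile 69.6). Ush1c (-0.49), Cib2 (-0.45) and Cdh23 (-0.42) were among the lowest, and Grxcr2 (0.45) and Xirp2 (0.39) the highest. Hair cell transcription factors stood at 0.03 (percentile 74.96), with Rorb at -0.46. Genes of the p53 and apoptosis list had 7 of 14 members detected in at least 37 cells and a median of 0.05 (percentile 83.2). Cdkn1a, a cell cycle inhibitor induced by p53, was detected in all 73 cells at a median of 321 CPM, and Pmaip1 and Phlda3 in 0. Immediate early and stress genes had a median of -0.23 (percentile 0.38), with 9 of 13 negative. Fos stood at -0.46 and Jun at -0.36, and Junb (0.28), Hspa8 (0.20) and Atf3 (0.17) at positive values. Genes of immature hair cells were mostly low: Atoh1 was detected in 0 cells, Sox2 in 4 and Tubb3 in 9, and the 5 members compared had a median of 0.15 (percentile 97.4). The 7 housekeeping genes stood at 0.08 (percentile 69.5) and the 16 general hair cell genes at -0.08 (percentile 15.3).

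**Figure D3:**
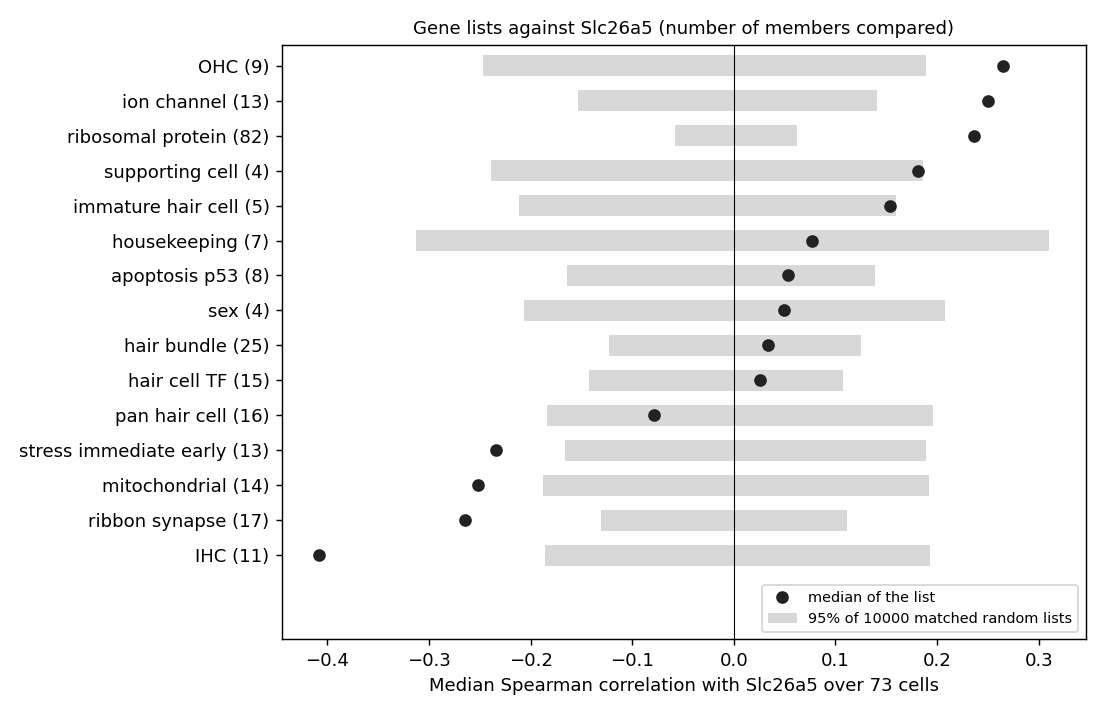
Points give the median rank correlation of each gene list with Slc26a5 over the 73 cells, and bars the central 95% of 10000 random lists matched on mean expression. Inner hair cell (-0.41), ribbon synapse (-0.26), mitochondrial (-0.25) and immediate early and stress (-0.23) genes lie left of their bars. Outer hair cell (0.26), ion channel (0.25) and ribosomal protein (0.24) genes lie right. The mitochondrial and ribosomal lists were added after the values were seen.

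Clustering without the genes of either list gave 4 clusters of 26, 23, 13 and 11 cells. All 4 had general, inner and outer hair cell markers, so they were left unnamed. Slc26a5 had medians of 452, 37.2, 48.7 and 0.1 CPM in clusters 1 to 4, and Atp2a3 had 0.5, 256, 185 and 1729 CPM. Ocm had medians of 4021, 2663, 1760 and 36.1 CPM, and Calb2 1809, 11046, 11981 and 7141 CPM. Slc17a8 differed less, at 978, 1683, 1528 and 1675 CPM. All 17 cells with Rprm were in cluster 1. The median score was -1.183, -2.280, -2.005 and -4.256. The median mitochondrial share was 5.08%, 6.37%, 8.01% and 9.14% in the same order, and the median total count fell from 18017474 in cluster 1 to 14612863 in cluster 4. A median of 12 of the 13 immediate early and stress genes was detected in cluster 4, against 10 in each of the others, and Hspa1a, Hspa1b and Fos were among its leading genes. The median library number was 48, 39, 38 and 21. The number of clusters was 3 at a Leiden resolution of 0.5 and 7 at 1.5. With 1000 variable genes it was again 4, but with different membership (adjusted Rand index 0.662), and the medians above hold for the clusters as first defined.

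Most markers of other cochlear cell types were detected in few cells, with a median of 6 markers detected per cell. Of 70 markers of supporting cells, neurons, glia, mesenchyme, blood, immune cells, endothelium and stria, 60 were detected in fewer than 10 cells. Their summed level had a median of 44.4 CPM and a maximum of 1616 CPM. At least 1 of these 60 reached 50 CPM in 22 cells. Without these 22 cells, though not without commoner markers, 64.7% of cells held both Slc26a5 and Slc17a8. Fbxo2, listed as a supporting cell gene, was in all 73 cells at a median of 5419 CPM, and the neurofilament genes Nefl and Nefm were in 70 and 64. The 4 supporting cell genes compared, Fbxo2 among them, had a median correlation of 0.18 with Slc26a5 (percentile 97.1). Summed per list, median levels were 252 CPM for neuronal, 45.5 CPM for glial and 4.22 CPM for mesenchymal markers, and under 1 CPM for blood, immune, endothelial and strial markers. Single members were more frequent: the immune marker C1qb was detected in 22 cells (maximum 307 CPM) and the glial marker Cnp in 29. Of the 9 immune markers, however, 6 were detected in no cell. Sox10, a glial transcription factor, was detected in 27 cells and correlated with Slc26a5 at 0.62.

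The most variable genes fell into transcripts carried by few cells and transcripts graded over many. Igkc, Ighm, Cd74 and Ly6d, genes of B lymphocytes, were detected in 1, 4, 2 and 1 cells. Their maxima of 2370, 2408, 1446 and 1044 CPM were all in library 5. Qpct was in 6 cells and Epyc in 2. Library 67 held the maximum of Epyc (698 CPM) and of 4 other markers of supporting cells, mesenchyme or glia, Lum (271 CPM), Gjb2 (161 CPM), Mal (120 CPM) and Fabp7 (91.5 CPM). Among genes detected in most cells, the list held Ocm, Calb1, S100a1, Nfkbia, Car2, Gpx2, Prxl2a, Calb2, Sirt2, Atp2a3, Igfbp5 and Clu. Rn7sk, a small nuclear RNA, was in 49 cells and Tspan8 in 22. S100a1, a calcium-binding protein, had a median of 1193 CPM and a maximum of 10914 CPM, and Gpx2, a glutathione peroxidase, had 4647 and 22475 CPM.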

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

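The tests of explanations in this part were chosen after the values were seen, while the uncorrected correlations between the lists and of Casz1 and the immature hair cell list were fixed before. The reporter element WPRE, outside the gene measurements, was read in all 73 libraries. Its lowest level was 44.1 CPM, above the 0.272 CPM that a count of 0 allows in the shallowest library, and its median was 144 CPM (maximum 429). Reporter level and Slc26a5 had a rank correlation of -0.08.

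Inner and outer hair cell transcripts varied against each other over the cells, with a median correlation of -0.179. Corrected for total counts and genes detected, the value was -0.175, and corrected for the mitochondrial share and immediate early genes it was -0.108. Both lay below the central 95% of random pairs of lists (lowest bounds -0.030 and -0.029), which were not matched on variability. The first value, nearly unchanged, argues against depth as the whole source. The latter correction shrank the value and used only stand-ins for RNA quality, so it cannot decide on RNA quality as the source. Admixed outer hair cell RNA would dilute inner hair cell transcripts alike only if outer hair cells lack them. That was not measured here, and Otof is also in the general hair cell list. For 6 of the 10 other members of the inner hair cell list, the ratio to Slc17a8 had a rank correlation of -0.3 or lower with Slc26a5. Atp2a3 was lowest (-0.73), Gata3 (-0.22) and Otof (0.00) were nearer 0, and Fgf8 (0.62) and Rprm (0.49) were positive. This test was chosen after the correlations of these genes were seen and cannot decide on admixture. Animal, picking batch and position along the cochlea stay open, since no label gives them (library number and Slc26a5 had a rank correlation of 0.315). The only biological hypothesis tested, on maturity, stood at percentile 97.4 with 5 genes and was left undecided.

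Library 5 alone carried a set of lymphocyte transcripts. A B lymphocyte picked along with the hair cell is a candidate source: of 18 B cell markers, listed after several had been seen, 14 were detected there and at most 2 in any other library, and 0 of 6 T cell markers were detected. Igkc, Ighm and Cd74 reached 2370, 2408 and 1446 CPM, while H2-Aa, H2-Eb1 and Cd22 had no read and H2-Ab1 stood at 1.64 CPM. Ebf1, counted among the 14, was detected in 70 other libraries. Misassigned reads from another of the 73 libraries are argued against, since the summed markers reached 8283 CPM there and at most 416 CPM elsewhere. Picking for both colours should remove a lymphocyte picked alone, but not one picked along with a hair cell. The library also held Slc17a8 (1683 CPM) and Otof (2459 CPM).

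Casz1 was read in cells labelled null, at a median of 42.1 CPM. The summed B cell markers could not test for reads misassigned between libraries. Their median in the other 72 libraries was 107 CPM, because Ebf1 is itself expressed in these cells. Igkc, Ms4a1 and Cd79b, at 2370, 525 and 361 CPM in library 5, reached at most 0.283, 0.226 and 0.141 CPM elsewhere. Cd79a and Ighm, by contrast, were detected in 2 and 3 other libraries. Mal and Fabp7 had 2128 and 1617 counts in library 67, and 8 and 4 in all other cells. Casz1 itself reached at most 283 CPM in any library, so these values argue against misassignment among the 73 libraries as the source of its median. Incomplete deletion and reads from remaining exons cannot be told apart here, because counts are per gene, and Casz1 and Slc26a5 had a rank correlation of -0.13 (-0.231 without the 22 cells with a rare marker of another type at 50 CPM or more). No biological explanation was tested.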

How the results depend on the processing

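Of 71 alternative values for 14 results, 56 stayed within the spread set for each, 15 moved and 0 reversed. A reversal was defined only for the score and the correlations within and between the lists, so the other values could not reverse. The count of 71 leaves out 14 values of the minimum on counts and genes per cell, which removed 0 cells and tests nothing. It includes 7 values after thinning to the shallowest library (11027945 counts), all equal to the unthinned ones, where 10 CPM is still 110 counts, so they say little about stability. The mitochondrial correction and the subset without cells in which a rare marker of another type reached 50 CPM were chosen after seeing the data. Leaving mitochondrial genes out of the totals moved none of the shares past their spread.

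The detection threshold moved shares by construction. At 1 count, Casz1 was detected in 97.3% of cells, both Slc26a5 and Slc17a8 in 94.5%, and a median of 12 markers of other cell types per cell. At 1 CPM Casz1 was in 87.7%. At 50 CPM Casz1 was in 42.5%, both genes in 56.2%, and a median of 14 general hair cell genes per cell was detected.

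With Pearson correlation the median was 0.282 within the inner hair cell list and -0.140 between the lists. Without the 2 cells farthest from the median Slc26a5 it was 0.281 within the inner hair cell list. Corrected for the mitochondrial share it was 0.180 within the inner hair cell list and -0.120 between the lists, and 69 genes reached 0.5 in size with Slc26a5 instead of 191. Without the 22 cells in which a rare marker of another type reached 50 CPM it was -0.216 between the lists, and the subset still holds commoner markers of other types. Leiden resolution 1.5 gave 7 clusters (adjusted Rand index with the main clusters 0.594), resolution 0.5 gave 3 (0.745) and 1000 variable genes gave 4 (0.662). The cause of these moves was not tested. Of the 30 genes named for Slc26a5, 21 to 28 stayed among the 15 highest and 15 lowest over the alternatives that changed the values. Of 124 values for single named genes, those of the minimum per cell and of thinning included, 20 moved and 0 reversed. Only the correlations among them, not the shares of cells, could reverse.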

Other observations

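The ribosomal protein and mitochondrial groups and the bounds of the maturity test were chosen after the values were seen, while the immature hair cell and sex-linked lists were fixed before. Cytosolic ribosomal protein genes mostly varied with Slc26a5 over the cells: 69 of 82 had positive rank correlations, with a median of 0.24, above all matched random lists. Transcripts of the mitochondrial genome went the other way, with 13 of 14 negative and a median of -0.25 (percentile 0.63). Among single genes of translation, Eef1a1, an elongation factor, stood at 0.63 and Rplp0 at 0.46, while the glycolytic enzyme Gapdh stood at -0.44. S100a1 (0.59), Nfkbia (0.60), Gpx2 (0.61) and Clu (0.62) also rose with Slc26a5.

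A hypothesis is that cells with more Slc26a5 may be less mature inner hair cells. The immature hair cell list stood at percentile 97.4 of matched random lists, but only 5 members were high enough to compare, which is too few to decide. Of these only Fgf8 (0.58) reached 0.5 with Slc26a5, and Mreg (0.40), Hes6 (0.15), Dll1 (0.14) and Jag2 (-0.08) did not.

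The sex-linked list had a median correlation of 0.05 with Slc26a5 (percentile 70.4). Y-linked genes were detected in 72 of the 73 cells, 70 of them with at least 2 of the 4 genes, and Xist reached at most 0.269 CPM. Xist overlaps its antisense partner Tsix, which reached at most 0.061 CPM, and how reads of such pairs were counted is not given in the sources used here. The median rank correlation between 2 cells over genes was 0.478 (range 0.369 to 0.580).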
